A study of Mus musculus with 2 samples.

How the data were processed

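Spleen RNA of 2 groups of mice was profiled by RNA sequencing, with 1 library per group. Per the labels, the genotypes were NOD.g7 and NOD.L7, and each library was made from the pooled spleens of 3 mice with a TruSeq RNA kit after RNeasy column extraction. The non-obese diabetic (NOD) mouse is an inbred strain that develops autoimmune diabetes. The series title calls the second kind of mouse NOD.Lc7, and the deposited table heads its columns NOD and NOD.LC7. The column with LC7 in its name was taken as NOD.L7 and the other as NOD.g7, and the labels do not say what g7, L7 or Lc7 stand for.

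The authors deposited 1 table of 22216 gene rows with a symbol, coordinates and 1 RPKM value per library (reads scaled to gene length and library size). CASAVA 1.8.2, SAMtools 0.1.18 and genome build mm9 are named per the submitters' processing notes. Gene stops on chromosome 1 reach 197002909, past the last gene of GRCm38 at 195323493, so coordinates are given here only as in the table, in mm9. The aligner's settings, the gene models, the strandedness and the treatment of reads with several matches are not given in the sources used here. Genes with many near-identical copies had low deposited RPKM values: Gapdh was listed at 2.04 and 2.03 in NOD.g7 and NOD.L7, Ppia at 7.13 and 6.15, and Hba-a1 at 0 in both, beside 2840 and 2839 for Actb. Of 83 ribosomal protein genes, 30 were under an RPKM of 20 in both libraries. Levels of such genes, and of members of multigene families, are therefore uncertain. A total of 14 symbols were duplicated.

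The depth was worked out from the steps of the deposited RPKM values. For single-exon genes shorter than 2500 bases, whose span in the table equalled the length of the only exon in GENCODE M21 (755 genes matched at any length), a low RPKM value times the gene's length was a whole multiple of what 1 sequenced base was worth. This held, within 0.15 of a whole number, for 100% of the 103 values used in NOD.g7 and 100% of the 115 used in NOD.L7. The steps corresponded to 9.13 Gb of mapped sequence behind the NOD.g7 values and 12.1 Gb behind the NOD.L7 values, a ratio of 1.32. Of these values, 15 in NOD.g7 and 20 in NOD.L7 were at whole multiples of 100 bases. The values thus count covered bases, and no count model was applied. For named genes the number of fragments was approximated from the RPKM, the longest GENCODE transcript and 200 bases per fragment, and a 95% interval of the fold was computed from an exact binomial interval (Clopper-Pearson) of the fragments given their sum. The fragment length and the way to the depth were chosen after the data were seen. These intervals cover counting error only. An unchanged gene of 1 kb at an RPKM of 1 would have about 45.6 and 60.4 fragments and a fold interval of 0.66 to 1.48.

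With 1 library per group the spread between mice or libraries cannot be measured, so no p-value, standard error or replicate check was possible, and every difference is one between these 2 libraries. Log2 ratios were computed as log2((NOD.L7 RPKM + 1)/(NOD.g7 RPKM + 1)), which understates the change of low genes. Genes with an RPKM of at least 1 in either library were kept, and a gene passed the size rule at an absolute log2 ratio of at least 1. The 32 gene lists, the size rule, the choice of named genes, the alternatives and the look at chromosome 7 were fixed before the data were examined. Older symbols of list members were matched through the RefSeq synonyms given with GRCm38, which added 14 matches. For lists with at least 5 kept members, the median log2 ratio was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins, and a list stood apart below the 2.5th or above the 97.5th percentile. Members of a list vary together in ways that random genes do not, so the percentile describes these libraries and is not a test between genotypes. Each chromosome's number of genes past the size rule was placed among 10000 expression-matched draws of as many genes. Counts in windows of 25 consecutive kept genes were set against the highest window in each of 1000 shuffles of gene order.

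Named genes were the 12 with the largest and the 12 with the smallest log2 ratio among genes past the size rule with an RPKM of at least 2 in either library, leaving out antigen receptor segments, olfactory receptors, Gm-numbered genes and small RNA genes. Added to these were up to 4 members of each list with the largest absolute log2 ratio and an RPKM of at least 1, up to 8 genes in any window that stood apart, and 8 genes fixed by name, such as Ins2, Cd3e, Foxp3 and H2-Ea, of which H2-Ea is not analysed here. Some genes that this rule names are not reported here. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at an RPKM of 5, centring of the median log2 ratio, a TMM factor (30% of ratios and 5% of levels trimmed) on the RPKM values, leaving out multigene families, random lists without matching, and windows of 50 genes. The calculations were tested on simulated data with the real mean levels and 11105 genes: the size rule recovered 0% of 50 genes changed 1.5-fold, 98% of 50 changed 3-fold, 97.9% of 48 changed 4-fold and 100% of 49 changed 8-fold, and passed 0% of 10830 unchanged genes. The simulation held counting error only, with every gene treated as 1 kb long. The genes counted as changed had a mean RPKM of at least 2. It therefore gives no rate of false passes between mice or libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.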

Results

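RNA sequencing of whole spleen compared mice of the NOD.L7 genotype with mice of the NOD.g7 genotype, each as 1 library from the pooled spleens of 3 mice. Of 22216 gene rows, 16378 were above 0 in NOD.g7 and 16482 in NOD.L7, and 11141 reached an RPKM of 1 in either library. The NOD.L7 values rested on 12.1 Gb of mapped sequence and the NOD.g7 values on 9.13 Gb. There were no replicates, so all values below are single measurements, and the counting intervals given with some folds leave out the variation between mice.

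The 2 spleen libraries had similar transcriptomes, with a small set of large differences. The most extreme was Gdpd3, a glycerophosphodiester phosphodiesterase family gene, at an RPKM of 1.53 in NOD.g7 and 108 in NOD.L7, a 70.2-fold difference (95% counting interval 56.6 to 89.1). In the other direction, the tumour necrosis factor receptor family gene Tnfrsf26 was at 11 in NOD.g7 and listed at 0 in NOD.L7. It was the 1 gene of those kept that was listed at 0 in a library. Hdc and Cd14 were among the genes furthest above in NOD.L7, and the red cell genes Slc4a1 and Rhd among those furthest below.

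Across the 11141 genes the log2 values of the libraries correlated with a Pearson r of 0.99. This is a correlation across genes, which are not independent replicates. The median log2 ratio was 0.02, and 86.4% of genes lay within 0.25 of 0. A total of 79 genes (0.71%) passed the size rule, 43 higher and 36 lower in NOD.L7. With the pseudocount of 1, which understates the change of low genes, 4 genes reached an absolute log2 ratio of 2, namely Gdpd3, Tnfrsf26, Slc4a1 and Hdc. By the plain ratio of RPKM values, further genes at low levels differed over 4-fold, such as Atp6v0e2, with an L7 to g7 fold of 0.0162 (counting interval 0.00476 to 0.0461) that rests on about 4 fragments in NOD.L7.

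Of the 12 genes furthest above in NOD.L7, Hdc was on the list of eosinophils, basophils and mast cells, Cd14 on that of monocytes and macrophages and Il1b on that of cytokines. Hdc, the histidine decarboxylase that makes histamine, was at 5.20 in NOD.g7 and 26.4 in NOD.L7, 5.08-fold higher (counting interval 4.76 to 5.42). The decoy interleukin-1 receptor gene Il1r2 was 5.46-fold higher, at 1.19 and 6.51. Cd14, the lipopolysaccharide co-receptor, was 3.82-fold higher at 7.64 and 29.1. Lrg1, a leucine-rich glycoprotein of neutrophil granules, was at 4.84 and 18.5, and the myeloid lectin receptor gene Clec4d was at 5.88 and 20.3. Il1b, which encodes interleukin-1 beta, was 2.65-fold higher at 29.4 and 77.9.

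The remaining genes of these 12 were Suclg2, Capg, Pppde2, Dmbt1 and Rsph1. Suclg2, a subunit of mitochondrial succinyl-CoA ligase, was 5.17-fold higher in NOD.L7, at 1.96 and 10.1. The actin-capping protein gene Capg was 3.28-fold higher, at 37.3 and 122. Pppde2 was 3.19-fold higher. Dmbt1 and Rsph1 were near the floor in NOD.g7, at 0.175 and 0.327, and at 2.24 and 2.63 in NOD.L7.

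Of the 12 genes furthest below in NOD.L7, 5 were on the erythroid list. Slc4a1, the anion exchanger band 3 of the red cell membrane, was at 22.1 in NOD.g7 and 3.97 in NOD.L7, 5.58-fold lower. The blood group gene Rhd was 4.29-fold lower, the erythroid nuclear protein gene Hemgn was 3.88-fold lower and Trim10 was 4.52-fold lower. Gzma, the granzyme A of cytotoxic lymphocytes, was 3.04-fold lower at 79.9 and 26.3 (L7 to g7 fold 0.33, counting interval 0.31 to 0.35). Casp4, an inflammatory caspase, was 3.28-fold lower at 13.2 and 4.04. Atp6v0e2, a subunit gene of the vacuolar proton pump, was at 2.10 in NOD.g7 and 0.0340 in NOD.L7, and Slfn9 was 5.18-fold lower. Mrgpre was 4.57-fold lower and Tmcc2 3.44-fold lower.

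The fixed lists asked which cell types and programmes of the spleen differed between the 2 libraries. Of 26 lists with at least 5 kept members, 9 had a median log2 ratio above the range of matched random lists and 7 below it. The largest shifts downward in NOD.L7 were in erythroid cells, Ly49 receptors and NK and cytotoxic cells. The largest upward were in germinal centre genes, monocytes and macrophages, and eosinophils, basophils and mast cells.

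**Figure D1:**
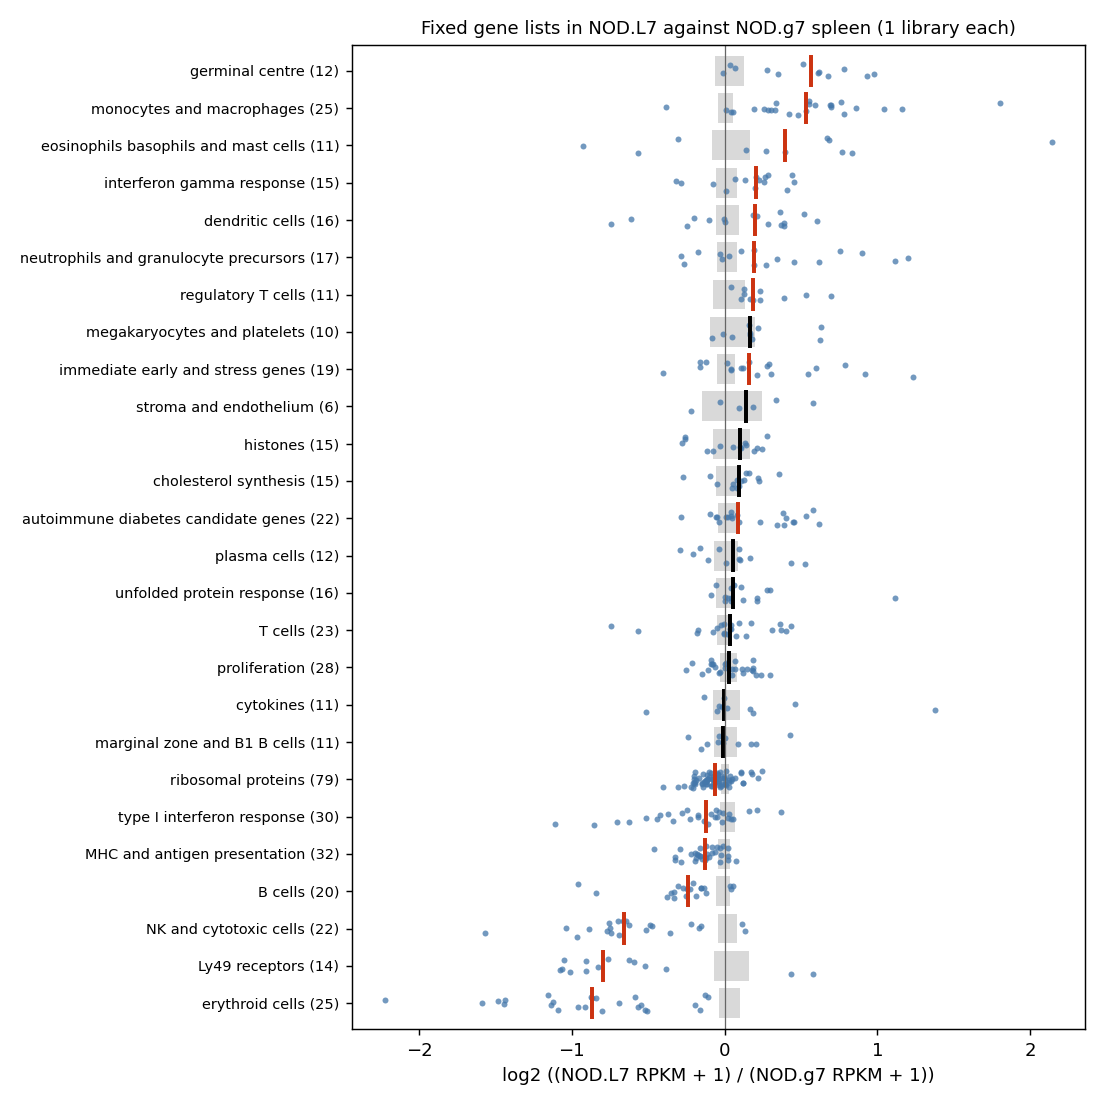
Log2 ratio of each kept member (points) of 26 fixed gene lists in NOD.L7 against NOD.g7, with the list's median as a vertical bar (red where it stood apart, black where it did not) and the central 95% of medians of matched random lists in grey; the number of members is in parentheses. The erythroid median was -0.87 and the germinal centre median 0.56, with all 25 erythroid members below 0.

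All 25 kept erythroid genes were lower in NOD.L7, with a median log2 ratio of -0.87 against -0.04 to 0.10 for matched random lists, and 9 passed the size rule. NK and cytotoxic genes had a median of -0.66, with 20 of 22 members lower and 2 past the rule, Gzma and Ncr1. Ncr1, an activating receptor of NK cells, was at 24.9 and 11.6. The NK cell receptor gene Klrb1c was at 5.91 and 2.53, and the transcription factor gene Eomes was at 12.6 and 6.35. The Ly49 receptors, a family of near-identical neighbouring genes on chromosome 6 whose reads cannot be assigned with certainty, had a median of -0.79. Of their 14 kept members 12 were lower, and Klra1, Klra8, Klra9 and Klra10 passed the rule at ratios of -1.05, -1.06, -1.01 and -1.08.

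B cell genes had a median of -0.24, with 17 of 20 members lower and none past the size rule. Fcer2a, the low-affinity IgE receptor of B cells, was at 257 in NOD.g7 and 132 in NOD.L7, and Cd55 was at 80.5 and 44.6. The germinal centre list went the other way, with 11 of 12 members higher, a median of 0.56 and none past the rule. Mef2b was at 2.29 and 5.46, Rgs13 at 1.83 and 3.87, and Mybl1 at 0.741 and 1.79. Plasma cell genes (median 0.05) and marginal zone and B1 genes (median -0.01, mean 0.03) lay within the random range, with Igj, the joining chain of secreted antibody, at 165 and 238.

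The pan-T cell list lay within the random range, with a median of 0.04 and 13 of 23 members higher. Cd3e was at 150 in NOD.g7 and 152 in NOD.L7. The co-receptors diverged, with Cd8a at 53.7 and 31.7, Cd8b1 at 81.8 and 54.9, and Cd4 at 106 and 136. All 11 kept regulatory T cell genes were higher in NOD.L7, at a median of 0.18 against -0.07 to 0.13 at random. None of them passed the size rule, and Foxp3, the lineage factor of these cells, was 1.48-fold higher at 13.4 and 19.9 (counting interval 1.41 to 1.56).

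Of 25 monocyte and macrophage genes 24 were higher in NOD.L7, with a median of 0.53, and Cd14, Cd163 and Vcam1 passed the size rule. Cd163, the haemoglobin scavenger receptor, was at 5.26 and 13.0, the adhesion molecule gene Vcam1 at 43.8 and 91.5, and the complement gene C1qb at 40.7 and 74.9. The neutrophil list had a median of 0.19, with 12 of 17 members higher and 2 past the rule. Those were the chemokine receptor gene Cxcr2, at 15.6 and 37.1, and Retnlg, at 16.4 and 36.8, and the granulocyte growth factor receptor gene Csf3r was at 39.0 and 73.7. The list of eosinophils, basophils and mast cells had a median of 0.39 with 8 of 11 higher, and Hdc alone passed. The 3 lower members were the mast cell protease gene Cma1, at 3.48 and 1.36, Il5ra, at 5.30 and 4.11, and Ear1, at 8.57 and 5.46. Dendritic cell genes had a median of 0.20, with 10 of 16 higher and none past the rule, and Ccr9 was at 11.3 and 6.34 while Itgax was at 20.8 and 30.3.

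The interferon-related lists had medians of opposite sign, and some members of each were little changed. The type I interferon response had a median of -0.12, with 23 of 30 members lower, and Rsad2, the antiviral protein viperin, was 2.61-fold lower at 6.71 and 2.57. Oas1a was at 2.60 and 0.988. The interferon gamma response had a median of 0.21, with 12 of 15 higher and none past the rule. The immunity-related GTPase gene Igtp was higher at 52.9 and 72.2, while Ciita was lower at 78.3 and 62.7. The cytokine list lay within the random range, with a median near 0 (-0.002) and a mean of 0.13, and of its 11 kept members Il1b alone passed the rule.

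Immediate early and stress genes, which respond to handling of tissue as well as to stimulation, had a median of 0.16, with 15 of 19 higher in NOD.L7. Fos passed the rule at 15.6 and 38.1, and Dusp1 was at 14.0 and 27.4. This shift stood beside those of the myeloid lists, in the same library. MHC and antigen presentation genes had a median of -0.13, with 28 of 32 lower and none past the rule, and the class II gene H2-Ab1 was at 1420 and 1252. The B cell list (median -0.24) was lower in the same library. The MHC and antigen presentation list lay within the random range, at a median of -0.07, when the H2 genes and other multigene families were left out. Most of its members are H2 genes, so a small list was left, with members such as B2m, Cd74 and Psmb8. Its place within the range may reflect that small size. Ribosomal protein genes had a median of -0.06, with 59 of 79 lower. Candidate genes of autoimmune diabetes had a median of 0.09, with 17 of 22 higher and none past the rule, and Slc11a1, an endosomal metal transporter, was at 12 and 18.9. The monocyte and macrophage list (median 0.53) and the regulatory T cell list (median 0.18), which share members such as Fcgr1 and Ctla4 with these candidates, were higher in the same library.

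Lists for proliferation (median 0.03), megakaryocytes and platelets (0.17), stroma and endothelium (0.14), the unfolded protein response (0.05), cholesterol synthesis (0.10) and histones (0.10) lay within the random range. In the unfolded protein response list Pdia4, a disulfide isomerase of the endoplasmic reticulum, was at 75.1 and 164 and was the 1 member past the rule. Of the pancreas list 2 genes were kept, Cela1 and Ctrl, and neither passed. Ins2 was listed at 0 in both libraries. The list of adipose tissue and mesothelium kept 1 gene, Fabp4, at 3.56 and 2.25. The 4 kept sex-linked genes were Y-linked and similar between libraries, such as Ddx3y at 30.5 and 31.9. Immunoglobulin segments and mitochondrially encoded genes had 0 kept genes, and the pattern for T cell receptor segments matched 1 gene, Tradd, which is not a receptor segment.

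The chromosomal comparison asked whether the genes past the size rule were spread evenly over the genome, chromosome 7 having been named first because of the 7 in the strain names. On chromosome 7, 17 of 867 kept genes (1.96%) passed, against 0.60% on the other chromosomes. Expression-matched draws gave 6.22 genes on average and an upper limit of 11. Chromosome 6 also stood apart, with 14 of 555 genes (2.52%) against 4.09 on average and an upper limit of 8. No other chromosome exceeded its upper limit, and the fewest for their draws were on chromosome 11, with 2 of 966 against 6.67 on average, and chromosome X, with 0 of 348 against 2.79.

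**Figure D2:**
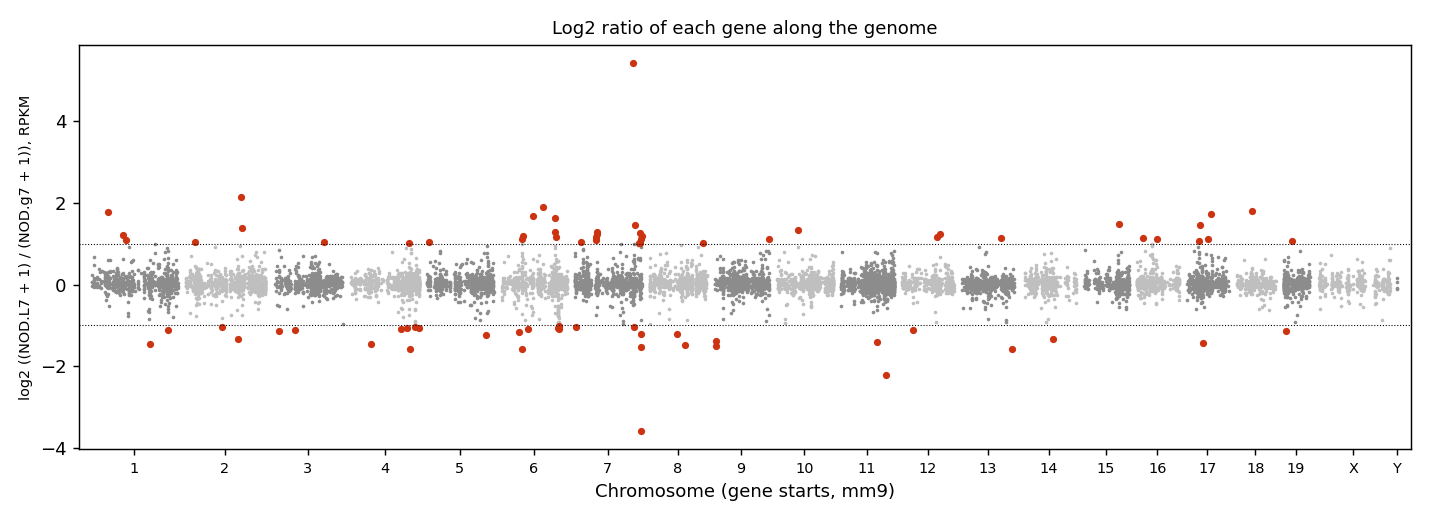
Log2 ratio of each of the 11141 kept genes in NOD.L7 against NOD.g7 (vertical axis) by gene start along the chromosomes in mm9 (horizontal axis); red points are the 79 genes past the size rule, whose limits are the dotted lines, and greys alternate between chromosomes. Chromosomes 6 and 7 hold 14 and 17 of the red points.

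The genes past the size rule lay in separate parts of chromosome 7, whose borders were set after the values were seen. From Gdpd3 (chromosome 7, 133909928 to 133919159) to the distal end, 11 of 172 kept genes (6.4%) passed, 7 higher and 4 lower. The gap before it was taken as the longest distance between neighbouring passing genes, so none of its 358 kept genes could pass. The distal part starts at a passing gene, which raises its share. Of the 337 genes proximal to the gap 6 passed, among them Ncr1. The windows held 1 region above the shuffled orders, from Trpm5 to Ccnd1 (150257434 to 152125830). Its highest window of 25 genes held 5 passing genes, against at most 4 in a window of any of the shuffles. The region's edges were trimmed to its first and last passing gene, which left 13 kept genes.

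Within that region Tnfrsf26 (150793590 to 150813750) was at 11 in NOD.g7 and listed at 0 in NOD.L7. Tnfrsf22 and Tnfrsf26 are related neighbours, so their levels are uncertain where reads could be shared, and sequence variants between the genotypes were not analysed here. Tnfrsf22 (150822630 to 150835543), a decoy receptor gene of the same family, was 3.41-fold lower in NOD.L7 at 4.15 and 1.22. Mrgpre (150964268 to 150970405), a receptor of the Mas-related family, was at 5.14 and 1.13. The ion channel gene Trpm5 was 12.5-fold higher, at 0.113 and 1.41 (counting interval 8.15 to 20.7). Ccnd1 (152115836 to 152125830), the cell cycle gene for cyclin D1, was 2.40-fold higher at 10.5 and 25.3. No window stood apart on chromosome 7 at a filter of RPKM 5, where the highest held 3 genes against a limit of 3, or at a pseudocount of 0.1, with 5 against a limit of 5.

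**Figure D3:**
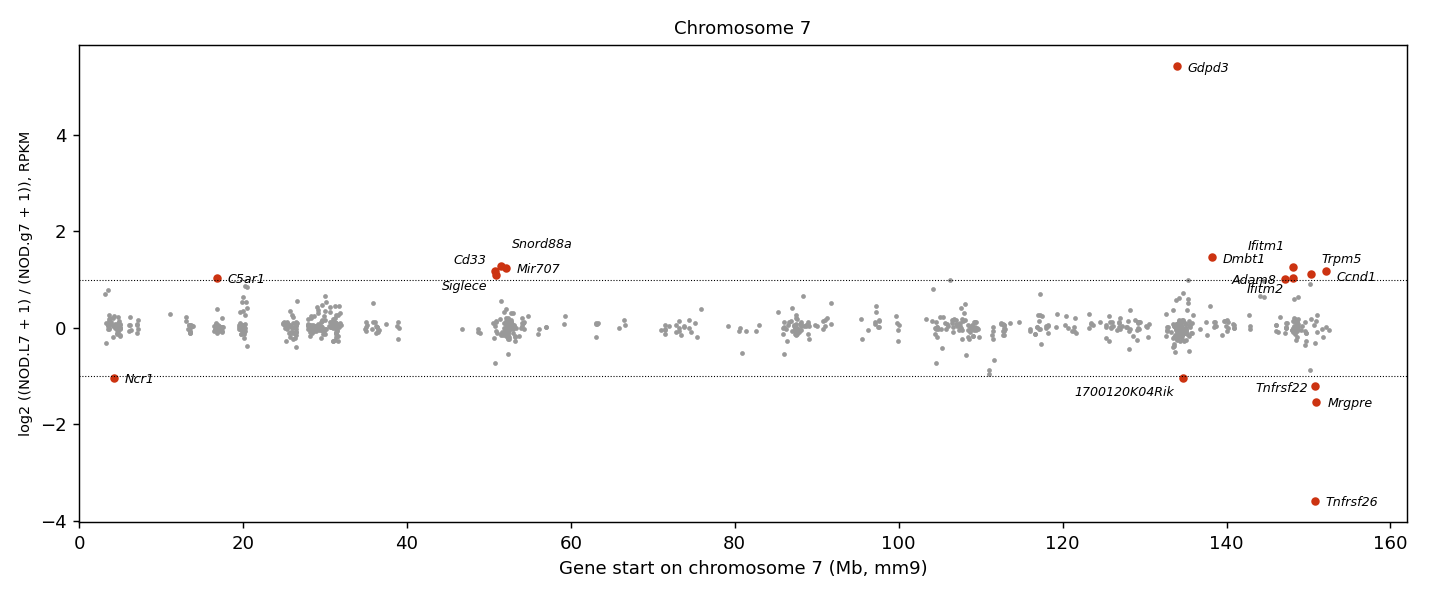
Log2 ratio in NOD.L7 against NOD.g7 (vertical axis) of the 867 kept genes of chromosome 7 by gene start in megabases of mm9 (horizontal axis), with the 17 genes past the size rule in red and named and its limits dotted. Of these, 11 lie from Gdpd3 to the distal end, and Tnfrsf26, listed at 0 in NOD.L7, is the lowest point.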

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

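With 1 library per genotype no setting can show how the results vary between mice, and no replicate could be left out. No paired analysis was possible because each genotype has 1 library. The number of genes past the size rule was 166 (91 higher, 75 lower in NOD.L7) with a pseudocount of 0.1 and 124 (67 higher, 57 lower) with 0.5, against 79 with 1, settings that admit lower genes by construction, and both held all 79. It was 52, with 19 lower, at a filter of RPKM 5, which tests fewer genes, and the share higher in NOD.L7 was then 63.5% against 54.4%. Median centring and the TMM factor each gave 76 genes, all among the 79. Chromosome 7 held 28 such genes with a pseudocount of 0.1 (upper limit of draws 20) and 11 at a filter of RPKM 5 (8), and chromosome 6 held 25 (15) and 9 (6), and both stood apart under every setting of pseudocount, filter, scaling and gene families. The highest 25-gene window on chromosome 7 held 3 genes at a filter of RPKM 5, at the limit of 3, and 5 at a pseudocount of 0.1, at the limit of 5, and so did not stand apart there; windows of 50 genes held up to 6, against a limit of 4. The median log2 ratio was 0.02 as deposited, 0.00 after median centring and -0.00451 with the TMM factor. Among results for single lists, 195 were the same, 1 was lost (MHC and antigen presentation, without gene families) and 5 were gained (cholesterol synthesis, megakaryocytes and histones). Of results for named genes, 867 were the same and 17 newly passed, counting only genes still kept under each setting. None that passed changed sign, but this says little. A pseudocount or filter cannot change the sign, and centring and the TMM factor moved the ratios by far less than the size rule. Depth limits genes near an RPKM of 1, where an unchanged 1-kb gene has a counting interval of the fold of 0.66 to 1.48.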

Other observations

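The counts per chromosome were planned, while the tests of explanations in this part were chosen after the data were seen, and the genes named here were chosen after their values were seen. Inside the neutrophil list, whose granule genes form no list of their own, members differed to unequal degrees between NOD.g7 and NOD.L7. Ngp was at RPKM values of 68.8 and 70.2, Ltf at 29.0 and 28.4, Camp at 39.1 and 34.5, Mpo at 3.07 and 2.34 and Elane at 1.64 and 1.20, while Mmp8 was 1.64-fold higher in NOD.L7, with Ctsg at 0.596 and 1.02 and Ms4a3 at 0.335 and 0.632. In the erythroid list Tfrc (16.3 and 14.5), Gata1 (3.05 and 2.72) and Nfe2 (9.85 and 9.05) were much closer than Alas2 (53.9 and 29.0), Car2 (41.9 and 18.6) or Spna1 (2.90 and 0.792), and the beta-globin transcript Beta-s was at 1253 and 680. Among Ly49 genes, Klra17 (12.2 and 18.7) and Klra2 (1.78 and 2.75) were higher in NOD.L7 while 12 were lower.

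Differences also lay side by side at other places. Casp1 and Casp4, adjacent inflammatory caspase genes on chromosome 9, were at 26.9 and 9.75 and at 13.2 and 4.04 in NOD.g7 and NOD.L7. In a stretch of related genes on chromosome 4, where the assignment of reads is uncertain, Gm13212 (4.25 and 1.78), Gm13139 (4.88 and 2.79), 2610305D13Rik (16.3 and 8.29) and Gm13157 (8.18 and 3.47) were all lower in NOD.L7. On chromosome 6, the lymphocyte GTPase genes Gimap3 (125 and 249) and Gimap5 (20.3 and 33.5) were higher, while Gimap9 was at 71.9 and 74.1. Next to the region that stood apart on chromosome 7, the tetraspanin genes Cd81 (82.3 and 156) and Tspan32 (63.0 and 34.0) went opposite ways. Inside that region Tnfrsf23, between Tnfrsf22 and Mrgpre, was at 0.758 and 0.0866, too low to be kept.

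Genes past the size rule were dense on chromosome 7, with 17 where matched draws had an upper limit of 11. These 17 include small RNA genes that rest on few fragments. Mir707 had about 1 in NOD.g7 and 10 in NOD.L7, and Snord88a about 3 and 17. Of the 17 genes, 29.4% went the less common way (12 higher, 5 lower). These directions argue only weakly against a one-way loss of reads that match the reference poorly in a single genotype, as the whole cause. The 5 lower genes include Ncr1, on the NK and cytotoxic list, and the related neighbours Tnfrsf22 and Tnfrsf26. With tandem families counted once and cell type genes left out, the lower genes were 1700120K04Rik, Tnfrsf26 and Mrgpre. Cells of another type in one pool stay open: with tandem families counted once and members of the cell type lists left out (10300 genes, 48 past the rule, 13 of them on chromosome 7) a window there held 4 passing genes (Trpm5, Tnfrsf26, Mrgpre and Ccnd1) against 3 in shuffled orders, but the lists do not hold every gene of a cell type, and whether these 4 follow one was not tested. Outside that window, C5ar1, Cd33, Siglece, Adam8 and Ifitm2, which are on none of those lists, were among the 13 and may follow myeloid cells. A chromosome 7 segment that differs between the genotypes and a deletion at Tnfrsf26 stay open as well, since the count of 17 is the pattern itself and neither sequence variants nor genomic coverage were analysed here.

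Chromosome 6 had 14 passing genes, and 11 were left, against an upper limit of 7 in draws, when the members of the fixed cell type lists were left out. With the fixed Ly49 list left out too, 7 were left against an upper limit of 6, and with all Klr and Clec receptor genes left out, a wider choice made after they were seen, 5 remained (Pdia4, Atp6v0e2, Npy, Capg and Suclg2) against an upper limit of 6 (10886 genes, 56 past the rule). Cells of another type in one pool therefore cannot be told apart from other explanations, because without the fixed lists the count stayed 1 gene above its limit and went below it only without genes picked after the fact. Reads of one genotype matching the reference better cannot be told apart from other explanations for those 5, of which 20% went the less common way, because they are too few. Pdia4, Atp6v0e2 and Npy start at 47746140, 48487568 and 49772728, with Atp6v0e2 lower and the others higher in NOD.L7. Whether they mark a chromosome 6 segment that differs between the genotypes was not tested.

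Digestive enzyme genes of the exocrine pancreas, an organ next to the spleen, were low in both libraries but uneven. Of 20 such genes above 0 in either library, 95% were higher in NOD.g7, and 11 of the 20 were listed at 0 in NOD.L7 against 0 in NOD.g7, in spite of the greater depth of NOD.L7. Ctrb1 was at 0.667, Pnlip at 0.568, Cpa1 at 0.458 and Cela2a at 0.446 in NOD.g7, each listed at 0 in NOD.L7, while Cela1 was at 2.29 and 2.65 and Ctrl at 1.40 and 1.34. The 20 genes summed to 8.81 in NOD.g7 and 4.50 in NOD.L7, and the 18 without Cela1 and Ctrl to 5.12 and 0.506. A trace of pancreas in the NOD.g7 library may explain this, and no biological explanation was tested.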
